A study of Pimephales promelas with 15 samples.

How the data were processed

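Messenger RNA was measured by sequencing in whole larvae of the fathead minnow (Pimephales promelas), a small freshwater fish used in toxicity testing. Each library came from a pool of 20 larvae taken 7 days after fertilization, and there were 5 libraries in each of 3 groups: solvent control, low HBCD and medium HBCD. HBCD (hexabromocyclododecane) is a brominated flame retardant that was fed to the parents, so the larvae received it through the egg. Per the labels' protocols, total RNA was extracted from the pools, polyadenylated RNA was selected, and strand-preserving libraries were made. A high dose group was not analysed here.

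Per the submitters' processing notes, the authors used Trim Galore, kallisto and DESeq2, and their versions and the kallisto reference are not given in the sources used here. The authors deposited 1 table of estimated counts per target and library, with 15551 rows and 15 libraries. These estimated counts are not normalized, and between 37.0% and 42.8% of the values in a library were whole numbers within a tolerance of 1e-06. An estimated count divides reads that match several similar sequences among them, so a target that shares sequence with a near-identical copy has an uncertain count. The authors also deposited 2 tables of their own comparisons against the solvent control. Per the file headers, those tables give the mean normalized count as a signal, the log2 fold change, the test statistic as a score, and the raw and adjusted p-value that the authors obtained for each listed target.

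Targets carried UniProt or RefSeq protein identifiers, and the files do not pair them with gene names. Of 14279 distinct identifiers, 0 matched the reference table of 64593 genes, so no gene symbol is given. The rule for named genes, fixed before the data were examined, took genes of largest change among those with a symbol, and it named none. The 46 gene lists fixed at the same time (pathways of xenobiotic metabolism, thyroid and estrogen signalling, stress, metabolism and immunity, and tissue markers) were not tested for the same reason, and neither were their alternatives. In place of that rule, the target of smallest p that rose and the target of smallest p that fell in each comparison with the control are given by identifier. This replacement was chosen after the values were seen.

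Several rows shared an identifier (793 identifiers on 2065 rows, at most 32 rows each). Estimated counts were summed per identifier and rounded to whole numbers. Summing was chosen after the row values had been seen, because the mean normalized counts in the authors' deposited tables matched the sums within 1% for 7 of 7 listed identifiers on more than 1 row in the low dose table and for 14 of 14 in the medium dose table, and matched the first row for 0 in either. The rows as deposited were run as an alternative. Of the identifiers, 184 had a total of 0.

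Changes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter with the groups, robust dispersions, and Benjamini-Hochberg adjustment over all targets tested at a threshold of 0.05. All 15 libraries entered 1 fit without covariates. The filter kept 13283 targets, which held 99.98% of the counts, and the common biological coefficient of variation was 0.273. The comparisons were low HBCD with control, medium HBCD with control, medium with low HBCD, and a trend over the rank of the group. Standard errors were derived from the F statistic and intervals cover 95%. Levels per library are CPM (counts per mega-count of the library) with TMM factors. Library totals ranged from 12.6 to 58.4 mega-counts (M) of estimated counts. At that depth and spread, the 95% interval of the fold change lay within 2-fold for 84.5% of targets in the low dose comparison, 84.7% in the medium dose comparison and 84.9% between doses.

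The test was tried on simulated counts with the real means, library sizes and dispersions. In the simulated low HBCD comparison, over 13142 targets, edgeR recovered 44.8% of 67 targets changed 1.5-fold, 68.7% of 67 changed 2-fold and 87.9% of 66 changed 4-fold, and 2.19% of its 137 calls were false. In the same simulation DESeq2 1.42.0, over 13283 targets, recovered 49.3%, 77.6% and 93.9% of these, and 21% of its 186 calls were false. Agreement between the dose groups was set against 20 simulations of unchanged groups with shared controls. The share of variance between groups was tested with 10000 permutations of the group labels, a test chosen after the data were seen.

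Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile normalization, no filter, a stricter filter, DESeq2, limma-voom (limma 3.58.1) with and without sample quality weights, non-robust dispersions, a replicate block, a threshold of 0.10, 1 surrogate variable (sva 3.50.0), a fit on the 10 libraries compared, dose as measured concentration, and leaving out each library. Rows as deposited, thinning of every library to 12.6 M counts, and leaving out the 2 deepest controls were added after the data were seen. DESeq2 gave no adjusted p for 78 of 14095 targets in each pairwise comparison, and these were left as missing. Tables were handled with Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.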

Results

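Gene expression was profiled in pools of 20 whole fathead minnow larvae, 7 days after fertilization, from parents fed HBCD or solvent only. Larvae of the low group held 0.576 mg HBCD per kg and their parents had received 11.5 mg per kg food, against 1.77 mg per kg in larvae and 36.4 mg per kg food in the medium group. Each group had 5 libraries. Totals, in mega-counts (M), were 13.03 to 58.4 M estimated counts in the solvent controls, 12.8 to 35.2 M in the low group and 12.6 to 26.4 M in the medium group. Solvent control replicates D and E, with 49.3 and 58.4 M, were the deepest libraries. The labels do not say whether pools came from separate parents, so p-values measure the spread between pools. They also leave open whether solvent control replicates D and E, which had the smallest log2 spread of the 30 pairs of libraries within groups, are separate pools or were sequenced in another run than the rest. Medium HBCD replicates D and E, and B and C, were also close, and 5 independent libraries in every group are assumed. Without solvent control replicate E, 5 targets were called in the low and 4 in the medium comparison, and without solvent control replicate D there were 0 and 1.

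**Figure D1:**
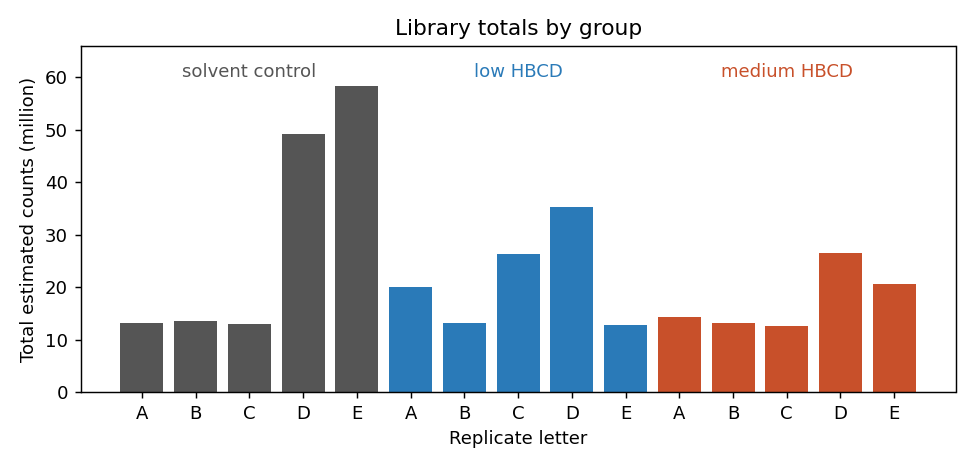
Total estimated counts per library in mega-counts, M (bars, axis from 0) by replicate letter, coloured by group. Solvent control replicates D and E reached 49.3 and 58.4 M, while the other 13 libraries lay between 12.6 and 35.2 M.

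The comparison of low HBCD with solvent control asked which transcripts differed in larvae with the lower body burden. Of 13283 targets, 2 rose and 5 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). XP_021327233.1 rose 6.16-fold, from 2.14 ± 1.43 CPM (SD, n = 5) in the controls to 12.9 ± 3.88 CPM (SD, n = 5), a log2 fold change of 2.62 (SE 0.37, edgeR adjusted p = 0.03109). Its 5 low HBCD libraries lay between 8.07 and 18.9 CPM, above the highest control at 4.54 CPM. Q6P0S5 fell from 18.045 ± 5.26 CPM (SD, n = 5) to 5.33 ± 0.966 CPM (SD, n = 5), a log2 fold change of -1.76 (SE 0.25, edgeR adjusted p = 0.03109), and its highest low HBCD library, 6.15 CPM, lay below the lowest control, 12.3 CPM. XP_021327233.1 and Q6P0S5 were picked for the smallest p in this comparison. That choice favours large fold changes and ranges that do not overlap, so the gaps add no support. E7FEJ8 also fell, by 0.41 on the log2 scale (SE 0.07, edgeR adjusted p = 0.04636), from 106 ± 5.71 CPM to 79.9 ± 7.40 CPM (SD, n = 5 each).

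At an unadjusted p under 0.05 the low dose comparison held 1016 targets, where 664.2 would be reached by chance. The number was 796 without solvent control replicate D, 738 without replicate E, 653 without both and 773 without low HBCD replicate D. The count of calls changed with single libraries: it was 0 without solvent control replicate C or D or without low HBCD replicate A, C or D, 1 without solvent control replicate B, 18 without solvent control replicate A and 12 without low HBCD replicate E, while it was 1 without the 2 deepest controls and DESeq2 called 95. Fewer libraries also lower the power of the test, and the 7 calls had edgeR adjusted p from 0.03109 to 0.04636. Lost power and reliance on single libraries were not told apart.

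Medium HBCD against solvent control posed the same question at the higher body burden. There 2 targets rose and 1 fell. Q6PWU7 rose 2.27-fold, from 5.22 ± 0.703 CPM (SD, n = 5) to 11.9 ± 2.64 CPM (SD, n = 5), with a log2 fold change of 1.18 (SE 0.16, edgeR adjusted p = 0.01318). The lowest medium HBCD library of Q6PWU7, 9.32 CPM, exceeded the highest control, 6.17 CPM. E7FEJ8 fell by 0.54 on the log2 scale (SE 0.07, edgeR adjusted p = 0.01178), to 72.8 ± 2.83 CPM (SD, n = 5), and its 5 medium HBCD libraries lay between 68.9 and 75.3 CPM, below the control range of 99.2 to 113 CPM. Q6PWU7 and E7FEJ8 were likewise picked for the smallest p in the medium dose comparison, which favours such gaps between the ranges. The other target that rose had a log2 fold change of 0.74 (edgeR adjusted p = 0.04745). XP_021327233.1, at 1.96 ± 0.456 CPM (SD, n = 5), had a log2 fold change of -0.10 with a 95% interval of -0.88 to 0.67, and Q6P0S5 one of -0.40 with an interval of -0.91 to 0.12.

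An unadjusted p under 0.05 was reached by 835 targets in the medium dose comparison, against 664.2 by chance, but by 658 without solvent control replicate D, 694 without replicate E and 677 without both. The count of calls was 0 without solvent control replicate C, 1 without replicate D and 6 without replicate A or B of the solvent control, while it was 1 without the 2 deepest controls and DESeq2 called 104. Fewer libraries lower the power of this comparison too.

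**Figure D2:**
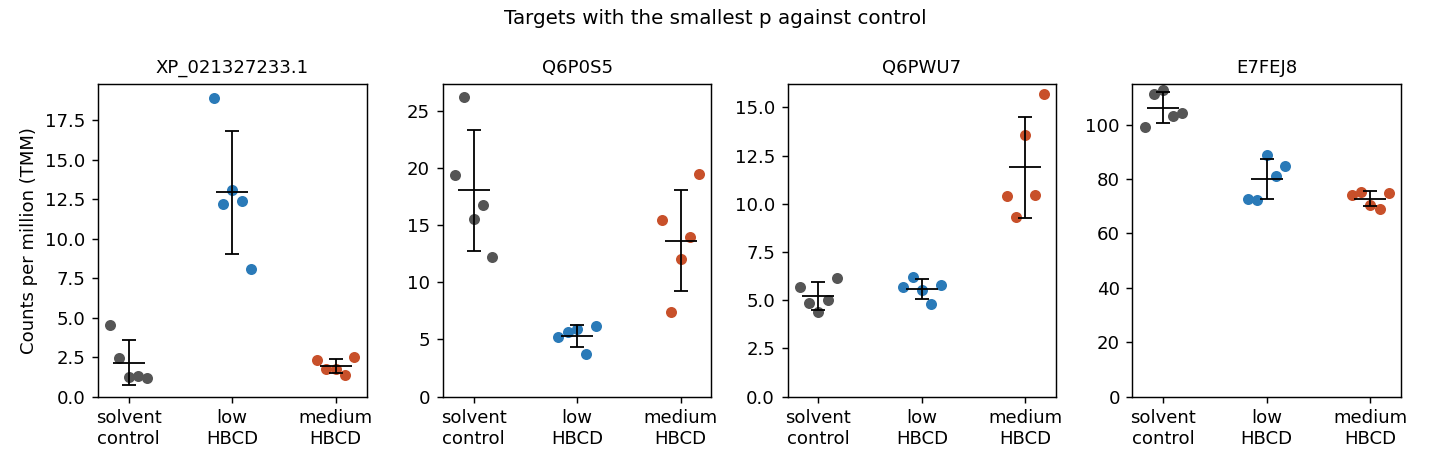
CPM (TMM scaled, linear axes from 0) of 4 targets in each library (points) of the solvent control, low HBCD and medium HBCD groups, with the group mean and SD (black bars, n = 5). XP_021327233.1 stood at 12.9 CPM in low HBCD against 2.14 in the controls and 1.96 in medium HBCD, and E7FEJ8 fell from 106 CPM in the controls to 79.9 and 72.8.

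Between medium and low HBCD, the comparison of the doses themselves, 11 targets were higher and 9 lower in medium HBCD. XP_021327233.1 was lower by a log2 of -2.73 (SE 0.37, edgeR adjusted p = 0.01186), while Q6P0S5 was higher by 1.37 (SE 0.25, edgeR adjusted p = 0.04835) and Q6PWU7 by 1.09 (SE 0.16, edgeR adjusted p = 0.01186). E7FEJ8 differed by -0.14 with a 95% interval of -0.28 to 0.01. Of the 20 targets, 17 had fold changes of opposite sign against the control in the 2 doses, a split that choosing targets by the difference between doses favours, and in 4 of the 17 the smaller of the 2 fold changes was under 0.1 in size. Of the 20, 16 were called against the control in neither dose. Over all 20 the median size of the log2 fold change between doses was 0.68, and 11 were below 1 in size. The count was 9 without medium HBCD replicate D, 12 without medium HBCD replicate A and 10 without low HBCD replicate D, and DESeq2 called 149. The call of Q6P0S5 was lost without any one of the 5 low HBCD libraries or of medium HBCD replicates A, C, D or E, with log2 fold changes between 1.21 and 1.42.

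**Figure D3:**
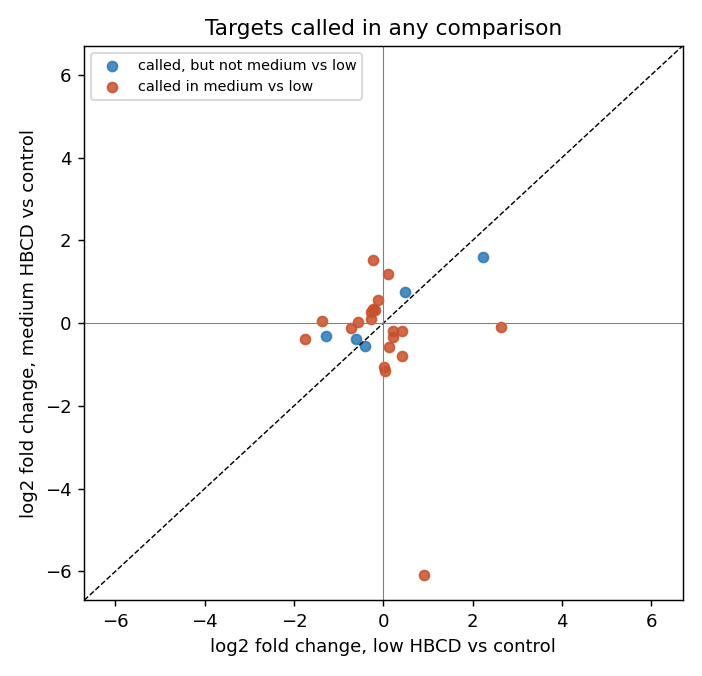
Log2 fold change against the solvent control in low HBCD (horizontal axis) and in medium HBCD (vertical axis) for the 25 targets called in any comparison, with the 20 called between medium and low HBCD in orange and the rest in blue. The dashed line marks equal values. Of those 20, which were chosen for a difference between the doses, 17 lie in the quadrants of opposite sign. The lowest point, at -6.09 in medium HBCD, is a target with 0 counts in 4 of the 5 medium HBCD libraries and 7 in replicate C, so its fitted fold change rests on those counts. This target also had only 1 count in solvent control replicate B, against 71 to 447 in the other controls.

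Over the rank of the dose, 1 target passed the test. E7FEJ8 fell by 0.27 on the log2 scale per step (SE 0.04, edgeR adjusted p = 0.03068). Q6PWU7 had a slope of 0.59 (SE 0.10, edgeR adjusted p = 0.06744). The call of E7FEJ8 was lost, and the count fell to 0, without any one of solvent control replicates B, C, D or E, low HBCD replicate D or medium HBCD replicates A to E, while its slope lay between -0.28 and -0.26 over 28 alternatives. Among these, dose as measured concentration gives a slope per mg per kg of larva and not per step. The labels give no concentration for the controls, which were set to 0 there. The count was 3 without solvent control replicate A or low HBCD replicate A and 2 without low HBCD replicate E, and with dose as the measured concentration 1 target was called, which was not E7FEJ8.

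Of the calls in the 2 comparisons with the control, 1 was shared, E7FEJ8, where independent lists would share 0.001581. Simulations of unchanged groups against shared controls set no chance level for it: 20 gave at most 0 shared calls, but edgeR called 0 targets in either comparison in 5 further simulations. Its call in low HBCD was lost in 13 of 23 alternatives. Across 13283 targets, which are not independent replicates, the fold changes of the low and medium groups had a Pearson r of 0.398 and a covariance of 0.0652. Unchanged groups simulated against shared controls gave a mean r of 0.509 and a mean covariance of 0.0677 (SD 0.00919 over 20 simulations). With the controls split 2 against 3, so that the comparisons shared none, the mean r was 0.0526 and the mean covariance 0.0146 over 20 fits (covariance from -0.0212 to 0.0329). At an unadjusted p under 0.05 in both comparisons, 89 targets were higher and 112 lower, where independent lists would share 13.7 and 18.5. The 201 targets compare with a mean of 132.5 and a highest value of 174 in the simulations. The simulations drew each target independently, without the structure among libraries described below, and so can understate the spread of this count. The 201 therefore do not show agreement beyond the shared controls. With the split controls, which leave fewer libraries per comparison, a mean of 66.35 targets had the same direction and 31.1 opposite directions. The groups accounted for 17.1% of the variance among libraries, against a mean of 14.3% for random groupings (permutation p = 0.0362, one-sided). The permutations treat the libraries as independent. Close pairs of libraries within a group, such as solvent control replicates D and E, can raise this share without an effect of HBCD. The p-value therefore does not single out HBCD.

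The authors' deposited table for low HBCD listed 99 targets, 38 higher and 61 lower, and the authors' deposited table for medium HBCD listed 105, 44 higher and 61 lower. Of these, 70 and 69 had log2 fold changes below 1 in size in the authors' deposited tables, and 9 and 15 had ones above 5. The authors' deposited tables shared 22 targets, 9 higher and 13 lower in both, where independent lists would share 0.119 and 0.264. The 2 comparisons share their controls, which by itself raises such an overlap. In 5 simulations of unchanged groups, where DESeq2 called at most 13 targets in a comparison, at most 1 was called in both. Those simulations also drew each target independently, so they set no chance level for the 22. In the edgeR fit, 92 of the 99 and 97 of the 105 targets in the authors' deposited tables were tested, all with the direction listed there and with an unadjusted p under 0.05, and 7.07% (exact 95% interval 2.89 to 14.03%) and 2.86% (0.593 to 8.12%) passed the adjusted threshold. These shares are of all listed targets, and their intervals treat targets as independent, which they are not. Those passing were all 7 and all 3 targets that edgeR called, so the number of edgeR calls capped the shares. With DESeq2 on all 15 libraries, 96.0% and 98.1% of the targets in the authors' deposited tables passed.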

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

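Library totals, targets with a count, the share of counts in the 10 most counted targets, the targets at 0 among those switching between libraries, and the CPM of the 4 targets given by identifier were searched for a library far from the rest of its group. Of 24 sets of 5 libraries, 0 held a value whose gap exceeded 0.71 of the range, a limit that chance passes in about 1 of 20 sets. The gap to the nearest library cannot single out 2 libraries that stand apart together, such as the controls with totals of 49.3 and 58.4 M.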

How the results depend on the processing

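Rows as deposited, thinning and the removal of the 2 deepest controls were chosen after the data were seen. Counts of calls are given in the order low with control, medium with control, medium with low, and dose trend, where edgeR on all libraries gave 7, 3, 20 and 1. DESeq2 called 95, 104, 149 and 56, limma-voom 26, 12, 18 and 4, and limma-voom with sample quality weights 571, 399, 43 and 172. With 1 surrogate variable there were 45, 21, 62 and 4. Non-robust dispersions gave 2, 3, 17 and 1. A threshold of 0.10 gave 21, 14, 24 and 6. The stricter filter gave 8, 5, 22 and 2, and upper quartile normalization 7, 7, 20 and 1. DESeq2 size factors and no filter left the counts within 1.5 times. A fit on the 10 libraries compared gave 0, 5 and 9, and rows as deposited 9, 16, 26 and 8. Thinning gave 0, 0, 12 and 0, and without the 2 deepest controls there were 1, 1, 13 and 0. Where edgeR gave 0, the unadjusted p was under 0.05 for 960 targets (low, 10 libraries), 992 (low, thinned), 816 (medium, thinned), 764 (trend, thinned) and 673 (trend, deepest controls out). Apart from the fewer samples or counts in some settings, the cause was not tested.

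The replicate letters are shared by the groups. With the letter as a replicate block the counts were 1, 0, 4 and 0 (801 targets at an unadjusted p under 0.05 for medium with control, 759 for the trend), and the r between doses was 0.442. Deviations of the 15 same-letter pairs from their group means correlated between -0.13 and 0.15, with 1 above 0.1. The median was 0.037, against -0.004 for pairs of other letters, and 4 of 15 libraries were closest to their own letter. A pairing of the libraries by letter was thus weak at most, and it was not tested.

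Leaving out 1 library gave 0 to 18 calls for low with control, 0 to 6 for medium with control, 9 to 22 for medium with low, 0 to 3 for the trend, and an r between doses of 0.330 to 0.481. With the controls split 2 against 3 the mean r was 0.0526. The share of the authors' deposited low list past the threshold was 96.0% with DESeq2 on all libraries and 71.7% on the 10 compared, and of the medium list 98.1% and 74.3%. XP_021327233.1 in low HBCD ranged from 2.24 (2 deepest controls out) to 3.31 (limma-voom with weights) on the log2 scale over 23 alternatives and lost its call in 9, Q6P0S5 in low HBCD from -1.94 to -1.59 over 24 and lost it in 10, Q6PWU7 in medium HBCD from 1.07 to 1.26 over 24 and lost it in 6, E7FEJ8 in medium HBCD from -0.57 to -0.51 over 23 and lost it in 4, and E7FEJ8 in low HBCD from -0.45 to -0.38 over 23 and lost it in 13. None of these 5 changed sign. The adjusted p ranged up to 0.1493, 0.1436, 0.08445, 0.07511 and 0.2275. Rows as deposited gave no single row for XP_021327233.1 or E7FEJ8. That setting is therefore missing from their 23 alternatives and from the 28 for the trend of E7FEJ8, and these targets were tested only with their rows summed.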

Other observations

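The share of on/off targets in the excess of DESeq2 calls and both tests of library depth were written after part of their result was seen; the definition of on/off targets was also set after the data were seen. Other regroupings of the libraries were run beside each count. For low HBCD with control, 2 of 100 splits of the 10 libraries, the real one included, gave edgeR as many calls as the real 7, and the highest other split gave 83. For medium HBCD with control it was 2 of 100, with 3 real calls and 132 in the highest other split, for medium with low HBCD 4 of 100, with 20 real calls and 1533 in the highest other split, and for the dose trend 3 of 100 regroupings, with 1 real call and 3 in the highest other. The median of the other draws was 0 calls for each of the 4 counts, so a grouping with any call already ranked high. In these draws the shares lay under 0.05, the limit for excluding chance. That holds only as far as the draws go: 26 of the 126 splits of each pair of groups were not run, the exact 95% intervals of the 4 shares reached up to 7.04%, 7.04%, 9.93% and 8.52%, and the trend had a single call. With DESeq2 chance cannot be excluded: 7 of 40 splits reached the real 95 (highest other 812), 2 of 40 reached 104 (highest other 141) and 5 of 40 reached 149 (highest other 2832). The exact 95% intervals of these shares were 7.34 to 32.8%, 0.611 to 16.9% and 4.19 to 26.8%. For medium HBCD with control, 2 splits, the real one included, reached the real count with either tool. There the unlike readings of the tools come from the unequal number of splits drawn. Splits that call several times the real number point to a structure of the libraries that the groups do not follow. The split with 1533 calls set low HBCD replicates A and B and medium HBCD replicates A, B and C against low HBCD replicates C, D and E and medium HBCD replicates D and E.

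DESeq2 called 172 distinct targets against the control in a dose where edgeR did not call them, some of which edgeR called in the other dose. Of these, 160 had an edgeR p under 0.05 before adjustment and 12 were not tested by edgeR. Targets that switch on and off between libraries made up 11.6% of them (exact 95% interval 7.25 to 17.4%), which argues against such targets as the bulk of the excess. In 5 simulations with no effect DESeq2 called at most 0.125 of the real number, although 39 of its 186 calls were false in a simulation with 200 changed targets. That argues against false calls as the bulk of the excess only for counts drawn independently per target with the edgeR dispersions. The simulations lack the structure among the libraries. Regroupings of the real libraries gave DESeq2 up to 812 calls for low HBCD with control, so false calls that come from that structure stay open. Which of the tools is nearer to the truth stays open.

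Of the 14095 identifiers with a count, 485 were on/off: at least 20 counts and 2 CPM in at least 2 libraries, and 0 in at least 2. Before rows were summed, 535 rows were on/off, and the ratio of on/off targets to these rows was 0.907. Of the 485, only 6 lie on more than 1 row, so reads moving between rows that share an identifier cannot account for the rest. The ratio was largely fixed by identifiers on a single row and cannot decide the question for the others. There were 12 pairs of targets exactly complementary over the libraries, against a mean of 8.21 and up to 17 in 200 shuffles. The shuffles moved states freely between libraries of unlike depth, so reads moving whole between targets of different identifiers stay open. The number of on/off targets at 0 fell with depth. It was 79 and 81 in the libraries of 58.4 and 49.3 M and 107 in that of 35.2 M. In the libraries of 12.6 to 14.4 M it was 174 to 219. Whether depth accounts for the switching stays open: the deepest library had a ratio of 0.492 to the mean of the others, between the limits set for and against it. That mean includes other deep libraries. Treatment group stays open too: states were shared more within than between groups by 1.45 percentage points, more than in random groupings (permutation p = 0.0333), but the difference lies below the bound of 2 points set against it, so both limits set for this test were met. Of the targets listed in the authors' deposited tables, 7 of 99 and 16 of 105 were on/off, among them all 3 and all 9 with log2 fold changes above 20 in size. Of the 485, 7 were at 0 in all 5 solvent controls, 10 in all 5 low HBCD and 25 in all 5 medium HBCD libraries, a difference that was not tested, and 0 were at 0 in all 5 libraries of 1 group and in no other library. Group and depth go together here: the largest total was 58.4 M in the controls, 35.2 M in low HBCD and 26.4 M in medium HBCD. Neither this count nor the sharing of states can tell group and depth apart. Close pairs of libraries within a group can also raise the sharing.

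Some libraries of a group were much closer to each other than the rest. Solvent control replicates D and E had a spread of 0.121 log2 units between them after every library was thinned to the same total, against a median of 0.290 over the 30 pairs within groups, a ratio of 0.416, which argues against their depth as the cause. Their counts differed by more than sampling noise (chi-square per degree of freedom of 16.3), which says nothing of whether they share a pool. After thinning, the spread was also low for medium HBCD replicates D and E (0.151) and B and C (0.173), and for solvent control replicates C and E (0.160). A shared pool, run, parent, spawning or day may lie behind such pairs, but the labels do not settle which, and no biological explanation was tested.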
